A study of Arabidopsis thaliana with 6 samples.

How the data were processed

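Total RNA of 3 Col and 3 hda9-1 samples was labelled with biotin and hybridised to Affymetrix ATH1 arrays, per the labels. The labels differ on the extraction, naming Trizol in the sample protocols and a column kit in the series' design text. The submitters' processing notes name RMA, affy and limma, without versions. The authors deposited 1 table of log2 values for all 6 arrays. Its values lie between 2.58 and 14.94, with medians of 5.42 to 5.46 per array, which fits the log2 scale of RMA. The settings of RMA are not given in the sources used here. RMA corrects background, sets the distributions of all arrays equal and summarises the probes of a set. A change that shifts most transcripts one way would therefore not be seen, and differences of dim probe sets are compressed. Arrays carry no count of reads, so the precision rests on the number of arrays.

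The table holds 22810 probe sets. The 64 control probe sets were left out of the tests, which left 22746, with no filter on dim probe sets. Probe sets were named only through the platform's annotation, updated through Entrez identifiers to the gene table of assembly TAIR10.1. Of those tested, 13513 were paired with 1 gene, 503 with several and 8730 with none in the annotation used here. Of the 13513, 13436 had their name updated through the identifier, 18 were matched by a mitochondrial symbol and 59 kept the platform's name. Together they stood for 13355 genes. A probe set without a listed gene is unnamed here, not without a gene, and no gene was named from a probe set with several. No genome build is stated for the array's design, so coordinates are not given and TAIR10.1 served only for names and gene order.

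All 6 arrays entered 1 limma fit (lmFit and eBayes without trend, limma 3.58.1 in R 4.3.3) with genotype as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, and a call is an adjusted p under 0.05. Log2 changes are hda9-1 minus Col. The labels number the replicates 1 to 3 in both genotypes. Deviations from the group means correlated between same-numbered arrays (r = 0.34, 0.21 and 0.21 across probe sets for replicates 1, 2 and 3), each over the limit of 0.1 set before the data were examined, and between −0.35 and 0.09 for other pairs. Each array correlated best with its own number. This evidence is limited, because the 3 deviations of a group cancel out, so the r values constrain each other. There are also few ways to match 3 arrays with 3, so such a match can arise by chance. The numbers were taken to pair the arrays on the evidence of the data alone, and what same-numbered arrays share was not tested. Values from a fit with the replicate number as a block are given beside those calls that it changes.

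The 23 gene lists were written from textbook knowledge before the data were examined, as were the tests of probe sets and lists, all alternatives below and the rule for named genes. Most tests of explanations were chosen after the results were seen, as the closing section states. The published study is known to describe photosynthesis genes, so the photosynthesis lists were not chosen blind. A scan of gene families by symbol and by synonym, a list of pollen genes and a count of neighbouring genes with the replicate block were added after the data were seen, and their results stand in the closing section. They cover light-harvesting antenna, photosystems and electron transport, Rubisco and Calvin cycle, chlorophyll synthesis, light signalling, seed storage proteins, oil body and seed oil, LEA proteins, seed maturation regulators, dormancy and abscisic acid, gibberellin, cell wall loosening, reserve mobilisation, heat shock proteins, histone deacetylases, flowering time, cell cycle and DNA replication, silique wall and secondary wall, seed coat, endosperm, reference genes, plastid genome and mitochondrial genome. Because many members have no probe set with 1 listed gene, 16 lists had 1 to 4 measured genes and were described only. The other 7, with at least 5, were tested with limma's camera at a preset correlation of 0.01, with camera at a correlation estimated from the residuals, and with fry, each adjusted over the 7 lists. Camera compares a list with the other genes, whereas fry tests it against no change. Camera with an estimated correlation also uses only the few residual degrees of freedom of the arrays. It can then miss real changes, so a call lost there does not show that a list is unchanged. A gene with several probe sets was represented by the brightest. In 4 untested lists the median and the mean differ in sign, namely gibberellin (−0.00 and 0.05), cell wall loosening (0.03 and −0.17), flowering time (0.00 and −0.01) and reference genes (0.02 and −0.02).

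The rule named HDA9, then the 12 genes with the largest increase and the 12 with the largest decrease among called probe sets with 1 gene whose 3 hda9-1 values all lay on one side of the 3 Col values, and then up to 4 called members per list or, where none was called, the 2 with the lowest p. All 870 called probe sets met the condition on the 3 values, as did 23.8% of all probe sets, where chance gives 10%. Other genes were named after their values were seen, namely PSAN, PSBW, PSBY, psbI, psbL, rpl32, psaB, nad5, PAP85, AT2G28490, ALC and those in the closing section.

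Alternatives were the replicate block, a filter on dim probe sets, eBayes with trend and robust (camera with trend only), cyclic loess, centring on the median, array weights, leaving out each array, stricter thresholds, 1 probe set per gene, an estimated correlation, the mean of a gene's probe sets, and probe sets with several genes. The fit was tested on simulated data with the spread of these 22746 probe sets in an hda9-1 against Col design. It recovered 20% of changes of 0.5 on the log2 scale, 70% of changes of 1, 98% of changes of 2 and 100% of changes of 3, with 1 unchanged probe set called. Each of these sizes was given to 50 probe sets only. The Benjamini-Hochberg cutoff depends on how many probe sets change, so these shares do not give the sensitivity of the real comparison. In 50 simulations without any change, 2 had a call, and 4 list calls were made over all 50. The simulated probe sets were independent of each other. These counts therefore do not show how often camera calls a list whose genes are correlated. Figures were drawn with matplotlib 3.10.9.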

Results

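Transcript levels were measured in dry Arabidopsis thaliana seeds of the wild-type accession Col and of hda9-1, a line with a T-DNA insertion in HISTONE DEACETYLASE 9 (HDA9), which encodes an enzyme that removes acetyl groups from histones. Seeds came from ripe siliques 18 to 19 days after pollination, on plants grown in 16 h of light at 22 °C and 8 h of dark at 16 °C. Each genotype was represented by 3 biological replicates, each pooled from siliques of several plants, and each of the 6 samples was hybridised to its own Affymetrix ATH1 array. The sample labels name dry seeds as the tissue, while the series' design text names dry siliques as the starting material. The deposited values were log2 expression values per probe set. With 3 arrays per genotype, the number of arrays limits the precision of every value below, and errors are the standard error (SE) of the limma fit or the SD over 3 arrays. No probe set was paired with HDA9, HDA10 or HDA17 in the annotation used here, so the HDA9 transcript was not analysed here and the genotype labels were not checked against it.

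The 6 arrays were closely alike. Across probe sets, which are not independent replicates, Pearson's r was 0.989 to 0.994 between Col arrays, 0.993 between hda9-1 arrays and 0.982 to 0.990 between genotypes. The first principal component held 46.9% of the variance and set all 3 Col arrays (scores −29.8 to −11.8) apart from all 3 hda9-1 arrays (20.5 to 25.6). The second component held 21.9% and placed Col replicate 3 at −25.8, the farthest of the 6 arrays from 0. In that array the 3′ probe set of actin exceeded its 5′ probe set by 1.58 log2 units, against 0.96 and 1.03 in Col replicates 1 and 2 and 1.17 to 1.28 in the hda9-1 arrays, and the 25S ribosomal RNA control read 12.16 against 11.05 to 11.43 in the other 5. For ubiquitin the 3′ excess was 0.87 in Col replicate 3, 0.61 and 0.62 in the other 2 Col arrays and 0.64 to 0.69 in the hda9-1 arrays, and for GAPDH it was 0.61, 0.33 to 0.36 and 0.30 to 0.54. Without Col replicate 3 the hda9-1 arrays were thus all steeper than the Col arrays for actin and ubiquitin, and not for GAPDH. None of the 64 control probe sets differed between genotypes at an adjusted p under 0.05 in limma, and 5 did at an unadjusted p under 0.05.

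The comparison asked which transcripts differed in dry seeds of the mutant. In limma, 312 probe sets were higher and 558 were lower in hda9-1 than in Col at an adjusted p under 0.05, out of 22746 tested. Among the probe sets with 1 gene, 137 were higher and 303 were lower. The genes that rose most included PRK (phosphoribulokinase, a Calvin cycle enzyme), TET3 (a tetraspanin) and DELTA-VPE (a vacuolar processing enzyme of the seed coat). The genes that fell most included GH3.3, which encodes an enzyme that conjugates auxin to amino acids, IAA30, an Aux/IAA gene of auxin signalling, and the chitinase family gene AT2G43580.

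Among the 12 genes with the largest increases, AT3G62550 went from 5.80 ± 0.37 (SD, n = 3) in Col to 8.18 ± 0.98 (SD, n = 3) in hda9-1, a log2 change of 2.39 (SE 0.44, limma adjusted p = 0.0341). PRK rose 3.19-fold, with a log2 change of 1.67 (SE 0.29, adjusted p = 0.0278). DELTA-VPE rose by 1.45 on the log2 scale (SE 0.31, adjusted p = 0.0496), a call lost after cyclic loess (adjusted p = 0.0524), and TET3 by 1.43 (SE 0.16, adjusted p = 0.00866). The other 8 were AT3G28270, AT5G44580, AT1G43590, AT5G60610, AT2G32160, AT5G66490, AT5G38980 and AT1G76960, with log2 changes from 1.62 for AT3G28270 to 1.27 for AT1G76960. Among the 12 genes with the largest decreases, AT5G54000 went from 10.28 ± 0.47 to 8.26 ± 0.12 (SD, n = 3 each), a log2 change of −2.03 (SE 0.22, adjusted p = 0.00866). AT2G43580 was 4.01-fold lower (log2 change −2.01, SE 0.18, adjusted p = 0.00617). GH3.3 was lower by 1.72 on the log2 scale (SE 0.35, adjusted p = 0.0414) and IAA30 was 2.94-fold lower (log2 change −1.56, SE 0.19, adjusted p = 0.0123). The other 8 were AT3G28155, AT1G17310, AT3G60730, AT5G24316, AT5G38195, AT3G61930, AT2G19460 and AT5G38780, with log2 changes from −1.78 for AT3G28155 to −1.53 for AT5G38780. For AT3G61930, 9.44 ± 0.11 in Col against 7.85 ± 0.12 in hda9-1, the adjusted p was 0.00207, the lowest of these 24 genes.

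The calls depended on single arrays. Of those 24 genes, AT5G60610, TET3, AT2G32160, AT5G54000, AT2G43580, AT3G60730 and AT3G61930 passed whichever array was left out, and none of the 24 changed sign. Total calls were 97 without Col replicate 1, 834 without Col replicate 2, 572 without Col replicate 3, 314 without hda9-1 replicate 1, 92 without hda9-1 replicate 2 and 296 without hda9-1 replicate 3. With the replicate number as a block, 625 probe sets were higher and 828 were lower, and 828 of the 870 calls of the fit without a block were among them. Of all probe sets, 4369 had an unadjusted p under 0.05, where 1137 would be called by chance.

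**Figure D1:**
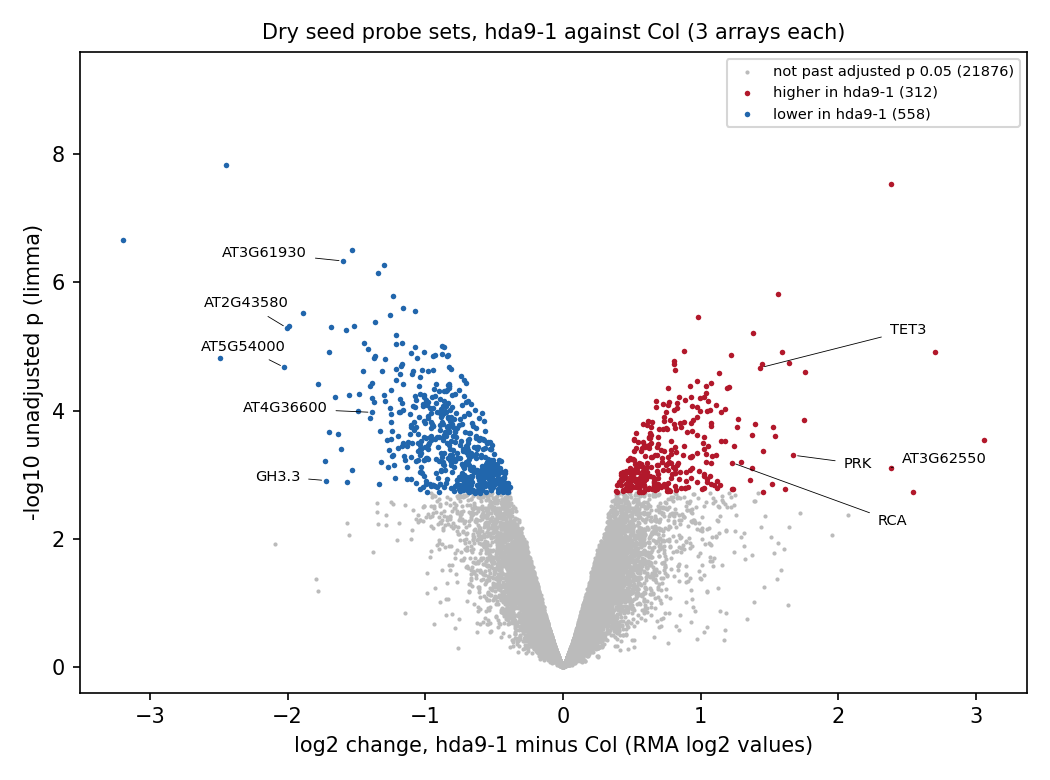
Each point is 1 probe set, with the log2 change (hda9-1 minus Col, RMA log2 values) on the x axis and minus log10 of the unadjusted limma p on the y axis, from 3 arrays per genotype. Red points (312) were higher and blue points (558) were lower in hda9-1 at an adjusted p under 0.05, grey points did not pass, and 9 genes are labelled.

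Several nuclear genes of photosynthesis rose in hda9-1 seeds. Of the listed genes, 3 of 19 were measured for the Calvin cycle, 5 of 31 for photosystems and 3 of 18 for the antenna. All 3 measured genes of the Calvin cycle list rose, namely PRK, RCA (Rubisco activase, log2 change 1.23, SE 0.22, adjusted p = 0.0313) and SBPASE (sedoheptulose bisphosphatase, log2 change 0.55, SE 0.11, adjusted p = 0.0444). RCA, the brightest of them, went from 9.81 ± 0.47 to 11.03 ± 0.16 (SD, n = 3 each), a 2.34-fold rise. In the list of photosystem and electron transport genes, 2 of 5 measured members rose, PSAE-1, a subunit of photosystem I (0.94, SE 0.17, adjusted p = 0.0342), and ATPC1, the gamma subunit of the chloroplast ATP synthase (0.89, SE 0.18, adjusted p = 0.0414). PSAN (1.44, SE 0.39, adjusted p = 0.0924), PSBW (0.85, SE 0.23, adjusted p = 0.0875) and PSBY (0.49, SE 0.21, adjusted p = 0.25) did not pass over all probe sets. All 5 passed when adjusted over the list alone, and 4 passed over all probe sets with the replicate block. The list's median log2 change was 0.89, and limma's camera called it up with an adjusted p of 4.35e-05. That call was lost with an estimated correlation (adjusted p = 0.223). Limma's fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.0627. Of the 5 measured chlorophyll synthesis genes, AT1G74470, the geranylgeranyl reductase gene, rose (1.08, SE 0.22, adjusted p = 0.0439), with the same count adjusted over the list alone. The median of that list was 0.18, and camera did not call it (adjusted p = 0.0523), nor with an estimated correlation (adjusted p = 0.223). It was called with the replicate block (0.0308), with trend (0.0469), median centring (0.0494) or array weights (0.0262), and without Col replicate 2 (0.0299) or Col replicate 3 (0.0260), while the adjusted p was 0.143 without Col replicate 1. The median was 0.10 without Col replicate 1, 0.39 without Col replicate 2, 0.28 without hda9-1 replicate 3 or with the dim filter, and 0.37 with array weights. None of the 3 measured antenna genes passed over all probe sets, with LHCB4.2 at 0.43 (SE 0.24) and LHCB4.3 at −0.53 (SE 0.17), and 1 was lower when adjusted over the list alone. In the light signalling list neither of the 2 measured genes passed, HYH at −0.04 (SE 0.13) and FHL at −0.05 (SE 0.11).

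The published study of these seeds is known to describe photosynthesis genes, so the photosynthesis lists were not chosen blind and their direction is not independent evidence. Without Col replicate 2 all 5 photosystem genes, the 3 Calvin cycle genes and AT1G74470 passed, without Col replicate 3 only RCA did, and without Col replicate 1 or hda9-1 replicate 1, 2 or 3 none of them did. SBPASE did not pass with the replicate block (adjusted p = 0.0540) or with trend and robust eBayes (adjusted p = 0.0508).

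**Figure D2:**
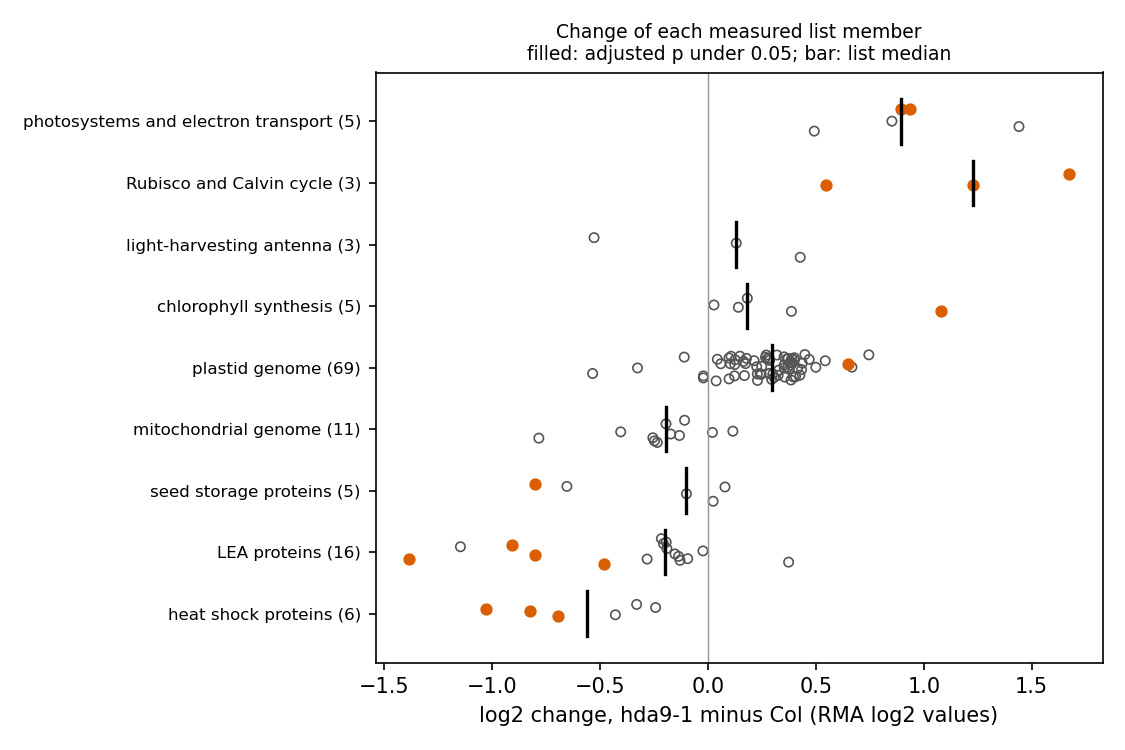
Each circle is 1 measured gene of a list, placed at its log2 change (hda9-1 minus Col, RMA log2 values) on the x axis, with lists on the y axis and the number of measured genes in parentheses. Filled circles had an adjusted p under 0.05 in limma, and the vertical bar is the median of the list, 0.89 for photosystems and electron transport and −0.56 for heat shock proteins.

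Transcripts of the plastid genome were measured through 69 genes, of which 64 had a positive and 5 a negative change. The median log2 change was 0.30. psbK, a small subunit of photosystem II, was the only one that passed over all probe sets (0.65, SE 0.11, adjusted p = 0.0288), and the only one when adjusted over the list alone. With the replicate block 3 passed, psbK, psbL and rpl32. psbI had the largest value (0.75, SE 0.18, adjusted p = 0.0654), while psaB was at −0.53 (SE 0.18, adjusted p = 0.158). The list was called up by camera with an adjusted p of 1.62e-06. The call was lost with an estimated correlation (adjusted p = 0.347). Against no change, fry gave an adjusted p of 0.329. Arrays of the 2 genotypes overlapped, since the list mean of Col replicate 3 stood 0.43 above the Col mean, and those of hda9-1 replicates 1, 2 and 3 stood −0.00, 0.49 and 0.33 from it. The median was 0.09 without Col replicate 2, 0.51 without Col replicate 3 and 0.45 without hda9-1 replicate 1. psbK passed without Col replicate 3 and in none of the other 5 leave-one-out fits. Of 11 mitochondrial genes none passed, over all probe sets or over the list alone, with cox2, a cytochrome oxidase subunit, at −0.78 (SE 0.21, adjusted p = 0.0913) and nad7 at −0.23 (SE 0.09, adjusted p = 0.216). A dimmer probe set of nad5, which the list did not use, was lower (−0.52, adjusted p = 0.0381), whereas the brighter nad5 probe set was at −0.17 (adjusted p = 0.806). The median of the mitochondrial list was −0.19, with a camera adjusted p of 0.0523 and, with an estimated correlation, an adjusted p of 0.347. Camera called this list down without Col replicate 1 (adjusted p = 0.0198), Col replicate 2 (0.0160) or hda9-1 replicate 2 (0.00791), and with median centring (0.0494) or the mean of a gene's probe sets (0.0245). The median was −0.30 without Col replicate 2, −0.02 without Col replicate 3, −0.29 without hda9-1 replicate 2 and −0.11 with array weights.

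Several genes of seed desiccation and heat shock fell in hda9-1 seeds. Of 16 measured LEA genes, whose proteins accumulate in drying seeds, 4 fell, the same number as when adjusted over the list alone, and 15 had a negative change. AT4G36600 fell from 12.49 ± 0.40 to 11.11 ± 0.12 (SD, n = 3 each), a log2 change of −1.39 (SE 0.19, adjusted p = 0.0140). AT2G42560 (−0.91, SE 0.18, adjusted p = 0.0403), AT5G27980 (−0.80, SE 0.14, adjusted p = 0.0297) and AT3G22490 (−0.48, SE 0.10, adjusted p = 0.0421) were the other 3. The median of the list was −0.20, and camera called it down with an adjusted p of 4.35e-05. That call was lost with an estimated correlation (adjusted p = 0.223). Against no change, and not against other genes, fry gave an adjusted p of 0.0329. Of 6 measured heat shock genes, 3 small heat shock protein genes fell, AT1G53540 (−1.03, SE 0.16, adjusted p = 0.0218), AT2G29500 (−0.82, SE 0.14, adjusted p = 0.0246) and AT1G52560 (−0.70, SE 0.15, adjusted p = 0.0476). When adjusted over the list alone 4 passed, and all 6 had a negative change. AT1G52560 did not pass with the replicate block (adjusted p = 0.0626), which left 2, or after cyclic loess (adjusted p = 0.0532). The median of the heat shock list was −0.56, and camera called it down with an adjusted p of 4.35e-05. This call too was lost with an estimated correlation (adjusted p = 0.223). Against no change, and not against other genes, fry gave the heat shock list an adjusted p of 0.0329. The LEA list kept 3 calls without Col replicate 2 or hda9-1 replicate 1, 1 without Col replicate 3 and none without Col replicate 1 or hda9-1 replicate 2 or 3. The heat shock list kept 3 without Col replicate 2 and none without any other array.

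**Figure D3:**
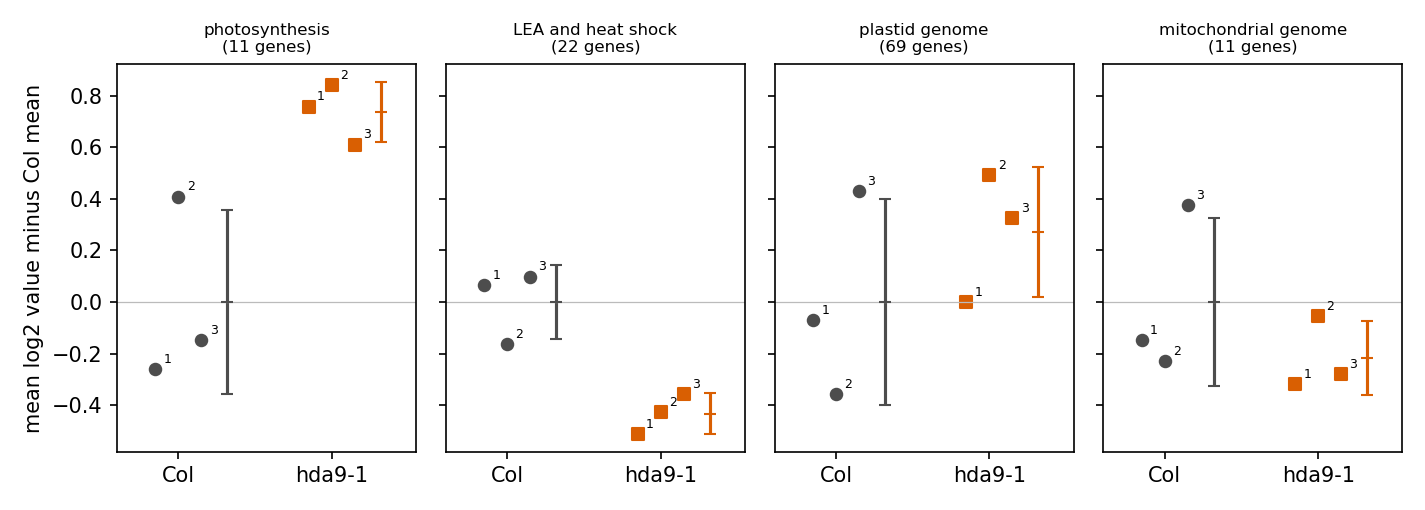
For each array (numbered by replicate; circles Col, squares hda9-1), the y axis gives the mean over the genes of a set of the log2 value minus the gene's Col mean, and bars show the mean ± SD of 3 arrays. The hda9-1 arrays lie above all Col arrays for the 11 nuclear photosynthesis genes and below all Col arrays for the 22 LEA and heat shock genes, while the genotypes overlap for the plastid and mitochondrial genomes.

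Genes of storage reserves gave 1 call. Of 5 measured seed storage protein genes, the cupin gene AT4G36700 fell (−0.80, SE 0.14, adjusted p = 0.0297), also when adjusted over the list alone, and of the leave-one-out fits it passed only in the one without Col replicate 3. The vicilin-like PAP85 was at 0.02 (SE 0.08) and AT2G28490 at 0.08 (SE 0.09). The list's median was −0.10, with a camera adjusted p of 0.122 and an adjusted p of 0.318 with an estimated correlation. The median was −0.04 without Col replicate 2, −0.19 without Col replicate 3 and −0.06 without hda9-1 replicate 3. Of 2 oil body genes, the oleosin gene OLEO3 was at −0.61 (SE 0.16, adjusted p = 0.0805, or 0.0292 with the replicate block), which passed when adjusted over the list alone, and AT3G01570 was at −0.13 (SE 0.09). In reserve mobilisation, ICL, the isocitrate lyase of the glyoxylate cycle, was at 0.47 (SE 0.17, adjusted p = 0.190, or 0.0425 with the replicate block) and the lipase gene SDP1 at −0.10 (SE 0.10).

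Regulatory genes were thinly covered, and none of the measured members passed over all probe sets. In seed maturation, EEL was at −0.16 (SE 0.17) and BZIP53 at 0.00 (SE 0.10). SPT, the single measured gene of the dormancy and abscisic acid list, was at −0.31 (SE 0.12, adjusted p = 0.233) and passed when adjusted over that list of 1 gene. Of 4 gibberellin genes, the receptor gene GID1A was at −0.23 (SE 0.11) and SLY1 at 0.46 (SE 0.27). Among histone deacetylases, HDA15 was at −0.32 (SE 0.13, adjusted p = 0.236) and HDA7 at 0.05 (SE 0.14). In the flowering time list of 3 measured genes, GI was at −0.13 (SE 0.14) and AGL19 at 0.08 (SE 0.10). PRL, the single measured gene of the cell cycle list, was at −0.15 (SE 0.11).

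The lists of cell wall genes and markers of other tissues gave 2 calls. EXPA4, an expansin, fell from 6.43 ± 0.12 to 5.60 ± 0.08 (SD, n = 3 each), a log2 change of −0.83 (SE 0.10, adjusted p = 0.0112), the only one of 4 measured wall-loosening genes to pass. ADPG1, a polygalacturonase of silique dehiscence, fell from 12.83 ± 0.02 to 12.32 ± 0.15, a log2 change of −0.51 (SE 0.10, adjusted p = 0.0399). ALC, the other measured gene of the silique wall list, was at 0.39 (SE 0.18, adjusted p = 0.285). Of 3 measured genes of the seed coat list none passed, with ARA12, a mucilage-related subtilase gene, at 0.31 (SE 0.10, adjusted p = 0.157) and BAN at 0.10 (SE 0.10). DELTA-VPE, the seed coat enzyme gene given above, is not in that list and rose (1.45, SE 0.31, adjusted p = 0.0496). AGL62, the single measured endosperm gene, was at 0.05 (SE 0.16). None of 3 reference genes passed over all probe sets, with AT2G28390 at −0.46 (SE 0.14, adjusted p = 0.113) and PEX4 at 0.40 (SE 0.15, adjusted p = 0.200), and both passed when adjusted over the list alone. Lists with fewer than 5 measured genes were not tested as a group, and EXPA4 did not pass without Col replicate 1 or hda9-1 replicate 2, while ADPG1 passed only without hda9-1 replicate 1.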

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

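The gene families, by symbol and by synonym, the pollen list and the count of neighbouring genes with the replicate block were added after the data were seen, and no other alternative was. Among the settings run, no called gene or list and no tested list median changed sign. Of 768 comparisons of a named gene with its value under an alternative, 613 kept their direction and side of the threshold, 11 changed sign, 140 were no longer past it (135 of them with 1 array left out) and 4 newly passed. The 11 were of genes that passed in neither fit. With 1 array left out BZIP53 ranged from −0.0754 to 0.0514, HYH from −0.126 to 0.0723, AGL62 from −0.0987 to 0.213, HDA7 from −0.106 to 0.128, FHL from −0.137 to 0.00234 and GI from −0.244 to 0.0195, and BZIP53 was at −0.0202 after cyclic loess and −0.0161 with array weights; the cause was not tested. The counts moved most. Probe sets higher in hda9-1 numbered 23 to 382 and probe sets lower 69 to 452 with 1 array left out, against 312 and 558. The fewest remained without Col replicate 1 (93 of the 870 calls kept) and without hda9-1 replicate 2 (86 kept). Fewer arrays widen the error, but why these 2 arrays mattered most was not tested. The replicate block gave 625 higher, and array weights, with Col replicate 3 at 0.51, gave 623 higher and 873 lower; the cause was not tested. By construction, a change of at least 2-fold left 70 higher and 141 lower, an adjusted p under 0.01 left 16 and 54, and 1 probe set per gene left 132 and 291. The dim filter, trend with robust, cyclic loess and median centring gave totals of 810 to 909. The 4 camera calls were lost only with an estimated correlation. The adjusted p was then 0.223 for photosystems, LEA proteins and heat shock proteins and 0.347 for the plastid genome. The estimated correlations (0.82, 0.23, 0.45 and 0.55) widen the null, and that setting also uses far fewer degrees of freedom. For chlorophyll synthesis, with an estimated correlation of 0.037, the unadjusted camera p still went from 0.0437 to 0.127. In the other settings the adjusted p of the 4 calls was at most 0.000568, 0.000376, 0.000295 and 0.0160. Chlorophyll synthesis newly passed with the block (0.0308), trend (0.0469), median centring (0.0494) and array weights (0.0262), and ranged from 0.0260 to 0.143 with 1 array left out. The mitochondrial genome newly passed with median centring (0.0494) and the mean of probe sets (0.0245), and ranged from 0.00791 to 0.698 with 1 array left out; these causes were not tested. The dim filter left 4 chlorophyll genes, too few to test. Apart from the changes given beside the results, the block changed no other call of a list or named gene. Signal over background was not analysed here, so the limit it sets for dim probe sets is unknown.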

Other observations

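The tests of neighbouring genes, of wild-type level and of other splits of the arrays were planned before their results were seen; the tests of photosynthesis, LEA and heat shock, plastid, Aux/IAA and pollen genes, those of neighbouring genes with the replicate block and of families with synonyms, were chosen after the result was seen, and all genes below outside the report were named after their values were seen.

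Some called genes outside the lists are given as values only. HPR, the hydroxypyruvate reductase of photorespiration, rose by 0.59 on the log2 scale (SE 0.10, limma adjusted p = 0.0234), and PSB27, a photosystem II assembly factor, fell by 0.78 (SE 0.12, adjusted p = 0.0203). A pair of autophagy genes went opposite ways, ATG8B at 0.43 (SE 0.09, adjusted p = 0.0409) and ATG8E at −0.52 (SE 0.11, adjusted p = 0.0469, or 0.0589 with the replicate block). MSRB5, a methionine sulfoxide reductase gene, rose by 1.18 (SE 0.19, adjusted p = 0.0218) and CML41, a calmodulin-like gene, by 1.07 (SE 0.21, adjusted p = 0.0386). The sugar transporter genes SWEET2 (−0.89, SE 0.13, adjusted p = 0.0180) and SWEET6 (−0.49, SE 0.09, adjusted p = 0.0354) fell, as did AtVEX1, also named SWEET5 (given with the pollen genes). These were 3 of the 16 genes with SWEET as symbol or synonym in the gene table, and camera did not call the 16 (adjusted p = 0.209). Of 51 genes with UGT as symbol or synonym, a count that leaves out glycosyltransferase genes without such a name, UGT76B1 (−1.16, SE 0.09, adjusted p = 0.00559), UGT72E1 (−0.94, SE 0.10, adjusted p = 0.00866) and SGT (−0.50, SE 0.09, adjusted p = 0.0341) fell and UGT73B1 rose (0.61, SE 0.09, adjusted p = 0.0168), and camera did not call the 51 (adjusted p = 0.725). Of the 870 called probe sets, 410 had no listed gene, among them the one with the largest increase (3.06 on the log2 scale), and 20 were paired with several genes, among them the one with the largest decrease (−3.20).

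Besides GH3.3 and IAA30, the auxin-related genes GH3.17 (−0.85, SE 0.17, adjusted p = 0.0432) and IAA34 (−1.19, SE 0.16, adjusted p = 0.0140) were lower. GH3.9 (−1.28, SE 0.34, adjusted p = 0.0879, or 0.0413 with the replicate block) and GH3.1 (−0.07, SE 0.09, adjusted p = 0.774) did not pass. All 7 measured genes with IAA as symbol or synonym had a negative change (6 of 7 after cyclic loess), with a median of −0.27, and IAA30 and IAA34 passed. This count leaves out Aux/IAA genes without a probe set of their own. IAA20, IAA29 and IAA33 were dim, with Col means of 4.06, 4.21 and 3.76 and changes of −0.05, −0.19 and −0.01. Gene families were formed by symbol after the data were seen, which gave 49 sets. The set of these 7 IAA genes was the only one of the 49 that camera called at the preset correlation (adjusted p = 0.0358, or 0.0230 with the replicate block). It kept IAA30 and IAA34, whose calls were seen before the families were formed, and was not tested without them. With an estimated correlation camera called none (adjusted p = 0.785 for the 7 IAA genes). With members by synonym added, the same 7 genes had an adjusted p of 0.0358, or 0.627 with an estimated correlation. The 20 genes whose names start with GH, which join GH3 with GH9 genes, were then called too (0.0360, or 0.627 with an estimated correlation). A decrease across the Aux/IAA family is therefore possible but stays open, and the 7 measured genes cannot speak for the members not measured.

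Some of the lower genes are known for expression in pollen, such as AT59, a pectate lyase gene (−1.02, SE 0.13, adjusted p = 0.0127), PLIM2a, an actin-bundling LIM protein gene (−1.18, SE 0.16, adjusted p = 0.0140), AtVEX1 (−0.86, SE 0.16, adjusted p = 0.0323) and the receptor kinase gene AT4G39110 (−0.75, SE 0.09, adjusted p = 0.0114). A list of 65 pollen genes was then written from textbook knowledge, of which 19 were measured. These 4 were lower, 15 of the 19 had a negative change (14 after cyclic loess) and the median was −0.30. Without the 4 genes already seen, none of the other 15 was called, 11 were negative, the median was −0.21, and camera gave an adjusted p of 0.00523 (0.0116 with the replicate block). With an estimated correlation the adjusted p was 0.264, so a decrease of pollen genes as a class may be present but is not settled. Most of the 19 were dim, with a median Col level of 4.50, below the median of 5.45 over all probe sets, and the brightest were PLIM2a (7.78) and PLIM2b (7.75, change −0.31, adjusted p = 0.355). Whether pollen or flower remnants on the siliques, or expression in the seed itself, gave these signals was not tested.

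The first pattern weighed is the rise of nuclear photosynthesis genes. Of the 11 measured antenna, photosystem and Calvin cycle genes 10 had a positive change, with a median of 0.85, and their mean was higher in hda9-1 in 9 of 9 pairs of arrays. These lists hold 18, 31 and 19 genes, so the 11 measured genes cannot speak for the rest. The steeper 3′ to 5′ gradient of Col replicate 3 is argued against as the whole cause, since the median was 0.686 without that array. A gradient that differs between the genotypes stays open, because without Col replicate 3 the hda9-1 arrays were steeper for actin and ubiquitin. Silique wall tissue in the hda9-1 samples stays open, as only 2 silique wall genes were measured, ADPG1 (−0.51) and ALC (0.39). An effect of the mutation stays open and untested.

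The second is the decrease of LEA and heat shock genes, where 21 of 22 measured genes had a negative change and the median was −0.26. These lists hold 25 and 17 genes, and the members not measured are not covered. The gradient of Col replicate 3 is argued against as the whole cause, since the median was −0.243 without that array and in 0 of 9 pairs of arrays was the hda9-1 mean higher. A decrease limited to a few members stays open, because the 95.5% with a negative change restates the pattern, 7 of the 22 were called, and both list calls were lost with an estimated correlation (adjusted p = 0.223 for each). Saturation of bright probe sets shrinks differences, so it could hide decreases of bright members but not produce the pattern. Whether it hid any was not tested. The gradient between genotypes and an effect of the mutation stay open.

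The third is the rise of plastid transcripts. Array-to-array spread unrelated to genotype may account for it, because the plastid mean was higher in hda9-1 in only 7 of 9 pairs of arrays. The exceptions both involved Col replicate 3 (0.43 above the Col mean), against hda9-1 replicates 1 (−0.00) and 3 (0.33). Col replicates 1 and 2 (−0.07 and −0.36) lay below all hda9-1 arrays. This test thus leans on Col replicate 3, which also had the highest mitochondrial mean (0.37). More organelle RNA of both kinds in the hda9-1 arrays would raise mitochondrial transcripts too, and no such rise was seen. Of 11 mitochondrial genes 9 had a negative change, and the mitochondrial mean was higher in hda9-1 in only 2 of 9 pairs. Without Col replicate 3 the mitochondrial median went from −0.19 to −0.02, against 0.51 for the plastid genes. These values go against a joint rise, but the mitochondrial means of the genotypes overlapped, so it is not excluded. An effect of the mutation on plastid transcripts stays open.

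Among 13216 measured genes in chromosome order, 434 were called, and 15 adjacent pairs were called in the same direction, all 15 lower. The median of 10000 shuffles was 8 pairs (3 to 14 in the central 95%; one-sided permutation p = 0.0163), so the count lay 1 pair above that range. With the replicate block, 713 of the genes were called, with 36 adjacent pairs in the same direction, 5 higher and 31 lower, against a shuffle median of 20 (12 to 29 in the central 95%; one-sided permutation p = 0.0008). Of the 15 pairs 14 were among them. Examples are AT3G25810 (−1.26) beside TPS-CIN (−1.04), both terpene synthase genes, and AT5G53990 (−0.61, adjusted p = 0.0476, or 0.0599 with the replicate block) beside AT5G54000 (−2.03). Shared regulation of neighbours may give this pattern. For those pairs that are tandem copies, so could probes that read similar sequences. Neither was tested, nor was it tested which of the pairs are tandem copies.

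Whether the increases came from genes silent in wild-type seeds stays open. Of the 312 higher probe sets 25.6% had a Col level below the median of all probe sets, and 11.3% of the lower ones did. The planned limit of 50% decides nothing, because dim probe sets were rare among the calls of both directions and the median does not mark silence. Judged by the mean over all 6 arrays, the shares were 17.9% and 18.6%.

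The 6 arrays can be split into 2 groups of 3 in 10 ways, too few for a share under 0.05. For single probe sets 1 of the 10 splits, the real one, gave as many as 870 calls, and the highest of the others gave 2. Every other split puts arrays of both genotypes in each group, so a genotype difference widens the error there. Few calls in those splits thus follow by construction, and the contrast of 870 with 2 does not test the real grouping. The replicate numbers were taken to pair the arrays, on the limited evidence of the data described above. The 3 other splits that part all 3 pairs gave 0 calls in limma each. They had 232 to 623 probe sets at an unadjusted p under 0.05, fewer than the 1137 expected by chance. For the 7 gene lists 2 of the 10 splits gave as many camera calls as the real one. The real split gave 4, and the one that puts Col replicates 1 and 3 with hda9-1 replicate 2 gave 5. Among the other splits only the one with Col replicate 1 and hda9-1 replicates 1 and 2 together gave 0, and the rest gave 1 to 5. Camera at the preset correlation thus also called lists in mixed groupings. Part of the genotype difference remains in each of them, so these calls do not measure a rate of false calls. With an estimated correlation each of the 10 splits, the real one included, gave 0 list calls, so that setting does not tell them apart.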
